A study of Danio rerio with 7 samples.

How the data were processed

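The samples were pools of mCherry-positive cells sorted from the ventricular apex of adult zebrafish (Danio rerio, 3 to 9 months old) after cryoinjury. Per the labels' protocols, fish carrying a postnb-driven, tamoxifen-inducible Cre and a loxP reporter received 10 µM 4-OHT at 3 and 4 dpi, and hearts were taken at 7 or 60 dpi. Tissue was dissociated with a mix of enzymes, and RNA came from pools of 3 to 5 hearts. The labels name both an amplifying single-cell RNA-seq kit, fed with 0.2 to 0.6 ng of RNA and amplified in repeated rounds, and a TruSeq kit, and reads of 60 nt were taken from one end on a HiSeq2500. Amplification from so little RNA can lose transcripts of low abundance at random, so a value of 0 need not mean absence.

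The authors deposited one table of TPM values, scaled to a fixed sum within each library, for 31388 gene IDs in 7 libraries. Per the submitters' processing notes, the tools were CASAVA 1.8.2, cutadapt and RSEM 1.2.25 with genome build Zv9; the aligner and the annotation release were not given in the sources used here. TPM divides each gene's estimated reads by its length and by the library's total, so abundant transcripts of one library lower all its other values, and no read depth is kept. RSEM shares reads among similar transcripts, so values of paralogs are uncertain. The values of 123 IDs with a mean TPM of at least 1 equalled those of another ID in all 7 libraries, in 33 sets, and the most abundant set of 6 IDs took 5.66, 29.1, 21.7 and 20.1% of TPM at 7 dpi and 9.54, 3.60 and 2.04% at 60 dpi. IDs were named with the supplied gene name table, which gave a symbol to 25925 of them (82.6%). Many of its symbols are shared by paralogs, which are told apart here by their IDs. No coordinates are given, since no genome was used here.

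Groups and replicate numbers came from the sample titles. Genes with a TPM of at least 1 in at least 3 libraries were kept (15130 genes). limma 3.58.1 in R 4.3.3 was fitted to log2(TPM + 1), with the time point as the only term and a mean-variance trend, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested genes at a threshold of 0.05. Fold changes are 60 minus 7 dpi on the log2(TPM + 1) scale, which understates the change of genes of low TPM, and errors of fold changes are standard errors. All adjusted p-values of single genes are limma's. Gene lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over 27 lists; camera with a correlation estimated per list and fry, which tests whether the members of a list move one way, were alternatives. Single values per library were compared with two-sided exact permutation tests over the 35 splits of 7 libraries. Bootstrap intervals of list medians and the permutation test between lists resampled genes, so they do not measure the spread between pools. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.

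The design, the 27 lists and the rule for named genes were written before the data were examined. Named genes were the 15 with the largest log2 fold change in each direction among genes past the threshold, with a mean of at least 10 TPM in the higher group, groups that do not overlap and an informative symbol; the up to 4 members of each list with the smallest p; and a fixed set of matrix, epicardial, mural, proliferation and cell type genes given in any case. Of 1005 list entries 943 were matched: 681 by symbol, 214 by the symbol without its paralog letter, 45 by an alias and 3 by a synonym. The matching without the paralog letter was chosen after the name table was seen, and puts all IDs of a shared symbol in a list. Some lists share members, such as MMP9 (proteases and neutrophils) and the C1q genes (macrophages and complement), so their results are not independent. The lists were fibrillar collagens, other collagens, basement membrane, matricellular and glycoprotein genes, resting fibroblast genes, collagen crosslinking, proteases, contractile genes, pericytes, epicardium, TGF beta, secreted signals, cell cycle, secretory pathway, oxidative phosphorylation, glycolysis, ribosomal proteins, immediate early and stress genes, complement and interferon, cardiomyocytes, endothelium, macrophages and general leukocytes, neutrophils, lymphocytes, erythrocytes and thrombocytes, neural cells, and cartilage, bone and tendon. The gene PDGFRB of the fixed set, also an entry of the pericyte list, was left out of the named genes, so its values are not given. A further ID named MPEG1 lay below the TPM minimum and was not tested.

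The fit was tested on simulated data with the measured spread of the real libraries, in 20 runs with 200 changed genes each among 15130. In these runs 0% of 2-fold and 7.6% of 4-fold changes were recovered, 5% of the calls were false and none had the wrong sign. Fewer genes changed in each run than passed in the real data (1041). The Benjamini-Hochberg threshold is stricter when fewer genes change, so these shares may understate recovery in the real comparison. A shifted list was called in 20 runs and a random list in 0. The noise was drawn independently for each gene, whereas estimated correlations within the real lists ran from -0.0602 (pericytes) to 0.583 (cardiomyocytes). The simulation therefore cannot show how often camera at a preset correlation falsely calls lists of correlated genes. Alternatives covered the pseudocount (0.1 and 5), the TPM minimum (none and 5), median ratio scaling, quantile normalization, replicate number as a block, library quality weights, robust variance moderation, leaving out each library, a minimum log2 fold change of 1 and the list tests. Alternatives added after the data were seen were TPM rescaled over IDs with a symbol, IDs without a symbol left out with TPM not rescaled, the fit without replicate 4 of both groups, IDs of equal values counted once, and the resting fibroblast list without MFAP4.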

Results

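RNA was profiled in cells sorted from the ventricular apex of adult zebrafish hearts at 7 and 60 days after cryoinjury (dpi), a freezing injury that the fish heart regenerates from. The sorted cells carried a permanent mCherry label, switched on by a Cre recombinase under postnb control in fish given 10 µM 4-hydroxytamoxifen (4-OHT) at 3 and 4 dpi. postnb encodes a periostin, a secreted matrix protein made by activated fibroblasts, so the label marks descendants of cells that used this gene early after injury. The comparison asks how the transcriptome of the labelled lineage differed between an early and a late stage of repair. There were 4 pools at 7 dpi (replicates 1, 2, 3 and 4) and 3 pools at 60 dpi (replicates 1, 2 and 4), each made from 3 to 5 hearts and from 0.2 to 0.6 ng of RNA. Values were TPM, a length-corrected transcript abundance, for 31388 gene IDs, which are scaled to a fixed sum in every library and keep no record of sequencing depth, so the depth behind each value is unknown. The p-values of single genes and of single values per library measure the spread between these pools.

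Libraries differed in how many genes they detected. At 7 dpi, 14599, 15305, 15431 and 9844 gene IDs had a TPM of at least 1 in replicates 1 to 4, and at 60 dpi 14061, 13352 and 10840 did in replicates 1, 2 and 4. The group means were 13795 ± 2659 (SD, n = 4) and 12751 ± 1692 (SD, n = 3), a difference within the spread between pools (two-sided exact permutation test, p = 0.514 over 35 splits). Gene IDs without a symbol took 31.2% ± 8.29 of TPM at 7 dpi and 17.4% ± 1.73 at 60 dpi (SD, two-sided exact permutation p = 0.0571). The mean Pearson correlation across tested genes was 0.784 within 7 dpi (0.695 to 0.882), 0.714 within 60 dpi (0.693 to 0.752) and 0.637 between groups (0.548 to 0.719), so single pairs overlapped. The first principal component, with 35.2% of the variance, placed all 7 dpi libraries on one side and all 60 dpi libraries on the other. The second, with 23.8%, set replicate 4 of each group, the library with the fewest detected genes, apart from the rest.

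**Figure D1:**
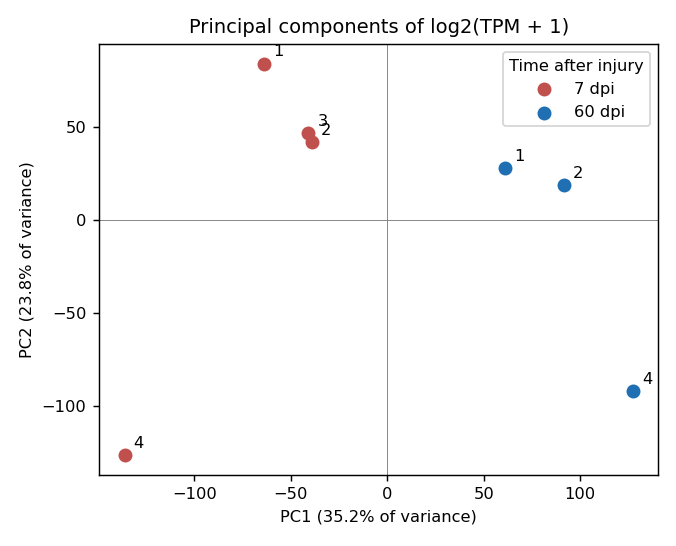
Principal components of log2(TPM + 1) over 15130 tested genes, with one point per library coloured by time after injury and numbered by replicate. Along PC1 the 7 dpi libraries lie between -136 and -39.0 and the 60 dpi libraries between 60.9 and 127; along PC2 replicate 4 of 7 dpi lies at -126 and replicate 4 of 60 dpi at -92.1.

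Expression in the sorted pools differed widely between the 2 stages. Leukocyte genes and one ID each of periostin and fibronectin were lower at 60 dpi, while some genes of resting fibroblasts, heat-shock and immediate early genes and ribosomal protein genes were higher. As lists, macrophage and leukocyte, resting fibroblast, stress and ribosomal protein genes passed with camera at a preset correlation but not at an estimated one (adjusted p = 0.0772, 0.216, 0.106 and 0.121), and the resting fibroblast call was also lost without any one of 4 single libraries. Of 15130 genes tested with limma, 1041 passed a Benjamini-Hochberg adjusted p of 0.05, and of these 484 were higher and 557 were lower at 60 dpi. A log2 fold change of at least 1 in size was reached by 1033 of them. In 3224 genes (21.3%) every library of one group lay above every library of the other, against 5.71% by chance. With TPM rescaled over the gene IDs that have a symbol, an alternative added after the data were examined, 378 genes were higher and 822 lower of 14050 tested, so that 31.5% of calls were higher in place of 46.5%. The median log2 fold change of the tested genes was then -0.27 in place of -0.04. With the same 14050 genes and TPM not rescaled, also added later, it was -0.05, and 47.8% of calls were higher. Without replicate 4 of both groups, also chosen after the data were examined, 411 were higher and 680 lower. The balance turned without 7 dpi replicate 1 (410 higher, 302 lower) and at a pseudocount of 5 (539 and 516). The total fell to 571 without 7 dpi replicate 3, to 580 without 60 dpi replicate 2 and to 643 without 7 dpi replicate 2. Higher genes numbered 281, 279, 213 and 287 without 7 dpi replicates 2 and 3 and 60 dpi replicates 2 and 4, and lower genes 362, 292 and 367 without 7 dpi replicates 2 and 3 and 60 dpi replicate 2.

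The 15 chosen genes with the largest decrease come first. grna.2, a granulin gene, fell from 584 ± 345 TPM (SD, n = 4) to 6.71 ± 11.1 TPM (SD, n = 3), a log2 fold change of -7.32 ± 0.83 (SE, limma adjusted p = 0.000694). dok2, an adaptor of blood cell signalling, fell by 6.04 ± 0.60 on the log2 scale (adjusted p = 0.000287). tnfa, which encodes the inflammatory cytokine TNF, fell from 74.7 ± 29.0 to 0.69 ± 1.195 TPM. The chemokine receptor gene cxcr3.3 fell from 142 ± 56.3 to 4.47 ± 2.56 TPM, and the immunoglobulin heavy chain gene ighm from 74.9 ± 55.7 to 1.19 ± 2.07 TPM. nkl.4, an NK-lysin gene, had a mean of 47.9 TPM at 7 dpi and was listed at 0 in all 3 libraries at 60 dpi, as were ifi27.6 (42.0 TPM at 7 dpi) and RGS13 (31.3 TPM at 7 dpi). The other members of this set were F13A1 (ENSDARG00000045453), c1qc, MFAP4 (ENSDARG00000090557), nkl.2, ccl34a.3, lgals3bp.1 and CTHRC1 (ENSDARG00000087198), with log2 fold changes between -5.68 and -4.79.

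The 15 chosen genes with the largest increase follow. GLUL (ENSDARG00000099776), a glutamine synthetase gene, rose from 10.2 ± 7.95 to 371 ± 123 TPM, a log2 fold change of 5.53 ± 0.75 (SE, limma adjusted p = 0.00184). HSD11B2, whose enzyme inactivates cortisol, rose from 5.95 ± 4.46 to 148 ± 45.5 TPM. HAS1, a hyaluronan synthase gene, rose from 6.33 ± 9.19 to 120 ± 47.4 TPM, and il15, which encodes a cytokine, from 3.04 ± 3.94 to 99.8 ± 19.9 TPM. The transcription factor genes MYC (ENSDARG00000007241), ZBTB16 and KLF9 rose to 714 ± 53.5, 64.3 ± 15.4 and 169 ± 74.9 TPM. abi3bpa, a matrix protein gene, rose by 5.18 ± 0.83 on the log2 scale, and cald1b, which encodes a caldesmon, from 5.28 ± 3.34 to 117 ± 19.8 TPM. col7a1l (ENSDARG00000093135) and or91a3 were listed at 0 in all 4 libraries at 7 dpi and averaged 30.6 and 21.8 TPM at 60 dpi. tcap, FAM219A (ENSDARG00000013813), COL8A2 and HSPB1 complete the set. The calls of KLF9 and tcap were lost without 60 dpi replicate 2 (adjusted p = 0.0508 and 0.0571), and that of nkl.2, in the first set, without 60 dpi replicate 1 (0.0503).

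One of 2 periostin IDs was far lower at 60 dpi. Of 2 gene IDs with the symbol POSTN, which the name table does not assign to postnb or its paralog, ENSDARG00000104267 fell from 948 ± 113 TPM (SD, n = 4) to 109 ± 24.8 TPM (SD, n = 3), a log2 fold change of -3.12 ± 0.26 (SE, limma adjusted p = 0.000101). The other, ENSDARG00000043806, had 124 ± 76.1 TPM at 7 dpi and 40.9 ± 4.39 TPM at 60 dpi and did not pass (adjusted p = 0.13). One fibronectin ID, FN1 (ENSDARG00000019815), fell from 514 ± 127 to 121 ± 55.5 TPM (adjusted p = 0.0044), whereas the more abundant FN1 (ENSDARG00000006526) had 2324 ± 338 and 1561 ± 263 TPM (adjusted p = 0.179). CTHRC1 (ENSDARG00000087198), a gene of collagen-producing cells after injury, fell by 4.86 ± 0.74 on the log2 scale.

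Fibrillar collagen transcripts stayed abundant at both stages. Of 11 tested fibrillar collagen genes, none rose and 1, col11a1b, fell, from 73.0 ± 15.2 to 24.1 ± 9.36 TPM (limma adjusted p = 0.0375, lost in 7 of 20 alternatives); 2 passed when adjusted over the list alone, both lower. col1a1a had 1046 ± 251 TPM at 7 dpi and 1493 ± 440 TPM at 60 dpi (adjusted p = 0.354), COL1A2 had 372 ± 52.9 and 375 ± 81.9 TPM (adjusted p = 0.999), and COL5A1 had 419 ± 79.0 and 363 ± 31.2 TPM (adjusted p = 0.735). The list did not shift as a whole against all other genes (camera, adjusted p = 0.599), and its median log2 fold change, 0.46, turned to -0.02 with quantile normalization. Among 10 other interstitial and beaded collagens 2 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.582; median 0.04, below 0 under median ratio, quantile and symbol-based scaling). Both COL12A1 IDs, which encode a collagen that decorates fibrils, fell, ENSDARG00000078322 from 690 ± 194 to 272 ± 66.4 TPM and ENSDARG00000019601 from 195 ± 22.4 to 68.2 ± 19.7 TPM. col16a1 rose from 130 ± 34.7 to 371 ± 117 TPM (lost in 7 of 20 alternatives), and COL8A2 from 0.23 ± 0.25 to 26.3 ± 11.3 TPM. No member of the basement membrane list passed, alone or over all genes (limma, 16 tested, 5 at an unadjusted p under 0.05; camera adjusted p = 0.46; median 0.23); COL4A1 had 101 ± 33.4 and 182 ± 6.10 TPM (adjusted p = 0.133).

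Matricellular and glycoprotein genes moved in both directions. Of 30 tested, 6 rose and 4 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.868), and the median log2 fold change, 0.07, lay below 0 with quantile and with symbol-based scaling. CCN1, which encodes a matrix signalling protein induced by growth factors and stretch, rose from 43.9 ± 13.3 to 558 ± 180 TPM, a log2 fold change of 3.64 ± 0.35 (SE, limma adjusted p = 0.000252). thbs2a, a thrombospondin gene, rose from 24.6 ± 0.78 to 208 ± 55.1 TPM (adjusted p = 0.000705). The tenascin ID TNC (ENSDARG00000021948) had 12.8 ± 7.74 and 12.9 ± 14.4 TPM, and TNC (ENSDARG00000078362) had 0.79 ± 0.70 and 1.39 ± 1.01 TPM, with adjusted p of 0.849 and 0.792.

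Of 28 tested genes of small leucine-rich proteoglycans and resting fibroblasts, 11 rose and 5 fell, or 13 and 7 adjusted over the list alone. The list as a whole had a median of 1.19 with a 95% bootstrap interval of -0.689 to 2.19, and a camera adjusted p of 0.037, or 0.216 with an estimated correlation. DPT, which encodes dermatopontin, a collagen-binding matrix protein, rose from 306 ± 147 TPM (SD, n = 4) to 1361 ± 99.9 TPM (SD, n = 3), a log2 fold change of 2.28 ± 0.36 (SE, limma adjusted p = 0.00413). SFRP1 (ENSDARG00000057678), a secreted Wnt antagonist gene, rose from 14.4 ± 5.41 to 192 ± 83.5 TPM, and fgl2b from 4.26 ± 2.82 to 89.2 ± 22.3 TPM. DCN, the decorin gene, rose from 492 ± 157 to 1112 ± 94.4 TPM (adjusted p = 0.0278). PDGFRA, which encodes a growth factor receptor of fibroblasts, had 19.7 ± 8.91 and 80.4 ± 12.0 TPM (adjusted p = 0.0226); both calls were lost without 7 dpi replicate 2 or any one of the 60 dpi libraries. Of the 5 members that fell 4 were IDs named MFAP4, a gene used as a macrophage marker in zebrafish, the most abundant of which, ENSDARG00000090783, fell from 1359 ± 332 to 194 ± 151 TPM. Without the 6 tested MFAP4 IDs, left out only after their values were seen, 11 rose and 1 fell (median 2.02; camera adjusted p = 7.6e-07, and adjusted p = 0.0617 with an estimated correlation). The call for the full list was lost without 7 dpi replicate 1 (adjusted p = 0.0541) and without 60 dpi replicates 1, 2 or 4 (0.0517, 0.0617 and 0.113).

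Of 12 pericyte and mural cell genes 2 rose and none fell (the same adjusted over the list alone), and 11 had a positive log2 fold change. The list had a camera adjusted p of 0.00073 and an adjusted p of 0.0772 with an estimated correlation. rgs5b rose from 112 ± 39.4 to 748 ± 167 TPM, a log2 fold change of 2.78 ± 0.34 (SE, limma adjusted p = 0.000924), and RGS5, a regulator of G protein signalling also used as a pericyte marker, from 3.75 ± 4.38 to 62.1 ± 8.03 TPM. In the epicardium list, genes of the outer layer of the heart, 2 of 19 rose and 1 fell (also over the list alone; camera adjusted p = 0.0597, median 0.80). The keratin genes krt4 and krt94 (lost in 9 of 20 alternatives) rose, krt4 from 103 ± 19.98 to 340 ± 93.2 TPM. The epicardial transcription factor genes TCF21, TBX18 and wt1b had 28.6 ± 14.2, 15.6 ± 4.17 and 69.7 ± 6.89 TPM at 7 dpi and 47.8 ± 20.1, 43.6 ± 20.2 and 84.1 ± 38.58 TPM at 60 dpi, with adjusted p of 0.45, 0.12 and 0.851. A separate ID named WT1 had 3.21 ± 4.74 and 13.4 ± 1.103 TPM (adjusted p = 0.151), and ALDH1A2, a retinoic acid synthesis gene, 79.2 ± 35.2 and 49.9 ± 17.9 TPM (adjusted p = 0.457).

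Matrix-degrading enzymes were partly lower at 60 dpi. Of 23 protease and inhibitor genes 5 fell and 1 rose, with the same counts over the list alone (camera adjusted p = 0.0597; median -0.29). CTSB, the lysosomal cathepsin B gene, fell from 2527 ± 543 to 464 ± 182 TPM, a log2 fold change of -2.49 ± 0.30 (SE, limma adjusted p = 0.000834). CTSK fell from 550 ± 123 to 150 ± 17.4 TPM, and MMP14 (ENSDARG00000008388), a membrane-bound collagenase gene, from 182 ± 22.8 to 60.9 ± 22.3 TPM. MMP15 (ENSDARG00000013072) fell by 3.43 ± 0.78 on the log2 scale. Markers of macrophages, which also express cathepsins, had a median log2 fold change of -2.19 in these libraries. Of 28 genes for collagen modification and crosslinking 2 rose and none fell, or 5 and none over the list alone (camera adjusted p = 0.147; median 0.15, and -0.07 with symbol-based scaling). They were loxl2a, a lysyl oxidase family gene, from 105 ± 26.2 to 369 ± 102 TPM, and P4HA2, a prolyl hydroxylase subunit gene, from 14.6 ± 7.48 to 61.9 ± 14.9 TPM (lost in 10 of 20 alternatives). LOX itself had 47.5 ± 28.9 and 50.4 ± 27.9 TPM (adjusted p = 0.924).

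Signalling genes moved both ways. In the TGF beta list 2 of 30 rose and 1 fell, or 7 and 1 over the list alone (camera adjusted p = 0.0199; median 0.58; adjusted p = 0.216 with an estimated correlation). The ligand gene tgfb1b fell from 19.7 ± 5.36 to 0.61 ± 1.05 TPM (limma adjusted p = 0.0122), while TGFB3 rose from 55.1 ± 29.0 to 181 ± 61.0 TPM (adjusted p = 0.0493). TGFBR3, a co-receptor gene, rose from 8.12 ± 4.16 to 38.9 ± 3.97 TPM; these 2 calls were lost in 12 and 10 of 20 alternatives. The list's call was lost without 60 dpi replicate 1 (adjusted p = 0.0593). Of 38 secreted signal genes 6 rose and 2 fell, or 9 and 6 over the list alone (camera adjusted p = 0.196; median 0.30). CXCL12, a chemokine gene of stromal cells, rose from 39.5 ± 5.47 to 157 ± 20.1 TPM, a log2 fold change of 1.97 ± 0.32 (SE, adjusted p = 0.00485). VEGFA (ENSDARG00000103542) rose from 9.07 ± 3.75 to 62.8 ± 15.4 TPM and IGF1 from 0.76 ± 1.19 to 28.2 ± 18.7 TPM, the latter not without 60 dpi replicate 2 or 4 (adjusted p = 0.0543 and 0.0511). WNT2B fell from 28.2 ± 8.73 to 0.32 ± 0.55 TPM. Of 27 contractile and smooth muscle genes 2 rose, cald1b and tpm4a (lost in 9 of 20 alternatives), and none fell, or 4 and 1 over the list alone (camera adjusted p = 0.196; median 0.31). acta2, the smooth muscle actin gene, had 63.7 ± 35.9 and 17.0 ± 20.1 TPM (adjusted p = 0.128). TAGLN (ENSDARG00000045408) had 288 ± 198 and 88.7 ± 13.2 TPM and TAGLN (ENSDARG00000033466) 256 ± 78.9 and 381 ± 42.2 TPM, with adjusted p of 0.0765 and 0.253.

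A few cell cycle and glycolysis genes were lower at 60 dpi, in libraries in which macrophage, lymphocyte and neutrophil markers had medians of -2.19, -1.81 and -1.78. Of 44 cell cycle genes 3 fell and none rose, or 6 and 1 over the list alone (camera adjusted p = 0.00277; median -0.95; adjusted p = 0.19 with an estimated correlation). TOP2A, a DNA topoisomerase gene of dividing cells, fell from 13.7 ± 6.82 to 0.01 ± 0.02 TPM (limma adjusted p = 0.0153), and RRM2 (ENSDARG00000020711) and plk1 also fell, although these 2 calls were lost in 10 and 14 of 20 alternatives. mki67 had 6.13 ± 3.00 and 0.66 ± 0.57 TPM and PCNA 64.0 ± 26.3 and 40.5 ± 11.9 TPM, with adjusted p of 0.157 and 0.46. CCNB2, a cyclin gene, went the other way, with 3.80 ± 3.95 and 43.0 ± 28.1 TPM, and did not pass (limma adjusted p = 0.0529). Of 25 glycolysis genes 4 fell, also over the list alone, and none rose (camera adjusted p = 0.0309; median -0.40; adjusted p = 0.498 with an estimated correlation). The pyruvate kinase gene PKM (ENSDARG00000099730) fell from 261 ± 61.3 to 61.9 ± 22.6 TPM and the enolase gene ENO1 (ENSDARG00000022456) from 755 ± 312 to 191 ± 30.3 TPM. This call was lost without 7 dpi replicate 1 (adjusted p = 0.0541), without 60 dpi replicate 1 (0.149), with fry (0.143) and with a replicate block (0.0598), and the median was -0.191 without 7 dpi replicate 1, -0.663 without 7 dpi replicate 4 and -0.768 without 60 dpi replicate 2. Of 70 oxidative phosphorylation genes 4 fell, none over the list alone, and none rose (camera adjusted p = 0.0597; median -0.36).

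Many ribosomal protein genes were higher at 60 dpi. Of 73 tested, 36 rose and none fell, or 57 and none over the list alone, and 72 had a positive log2 fold change (median 0.94; camera adjusted p = 4.8e-30; adjusted p = 0.121 with an estimated correlation). RPS28 rose from 606 ± 55.6 to 1669 ± 126 TPM, a log2 fold change of 1.46 ± 0.23 (SE, limma adjusted p = 0.00343). The list median was 0.49 with quantile normalization. Of 66 secretory pathway and protein folding genes 1 rose and 1 fell, also over the list alone (camera adjusted p = 0.0102; median -0.59; adjusted p = 0.498 with an estimated correlation). These were SEC61G, a subunit of the protein channel of the endoplasmic reticulum, from 405 ± 140 to 1163 ± 209 TPM, and LMAN2, a cargo receptor gene, from 61.1 ± 15.6 to 14.2 ± 1.37 TPM.

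Leukocyte transcripts were abundant in the sorted cells at 7 dpi and much lower at 60 dpi. Of 43 macrophage and general leukocyte genes 29 fell and none rose, or 37 and none over the list alone (median -2.19; camera adjusted p = 4.1e-27; adjusted p = 0.0772 with an estimated correlation). c1qb, which encodes a complement chain made by macrophages, fell from 466 ± 112 TPM (SD, n = 4) to 36.9 ± 8.59 TPM (SD, n = 3), a log2 fold change of -3.62 ± 0.31 (SE, limma adjusted p = 0.000127). laptm5, a lysosomal gene of blood cells, fell from 276 ± 83.1 to 31.2 ± 13.8 TPM. The IDs named MPEG1, a macrophage pore protein, had 172 ± 50.7 and 99.6 ± 52.1 TPM (ENSDARG00000043093) and 84.8 ± 42.1 and 41.9 ± 52.1 TPM (ENSDARG00000055290), with adjusted p of 0.233 and 0.183. In the lymphocyte list 7 of 20 fell and none rose, or 10 and none over the list alone (median -1.81; camera adjusted p = 4.06e-08; adjusted p = 0.0772 with an estimated correlation). In the neutrophil list 2 of 15 fell, MMP9 (lost in 8 of 20 alternatives) and CXCR4 (ENSDARG00000041959), and none rose, or 7 and 1 over the list alone (median -1.78; camera adjusted p = 0.000227; adjusted p = 0.0772 with an estimated correlation). MMP9 also belongs to the protease list and CXCR4 to the lymphocyte list, so these falls are not separate from those reported there.

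Blood and immune effector genes followed the same direction in part. Of 23 erythrocyte and thrombocyte genes 4 fell and none rose, or 11 and none over the list alone (median -1.95; camera adjusted p = 9.12e-07; adjusted p = 0.19 with an estimated correlation). itga2b, a thrombocyte integrin gene, fell from 58.1 ± 39.4 to 1.71 ± 2.51 TPM (limma adjusted p = 0.00642). The haemoglobin gene hbaa1 had 4210 ± 1418 and 3099 ± 2371 TPM (adjusted p = 0.426). Of 27 complement and interferon genes 7 fell and 2 rose, with the same counts over the list alone (camera adjusted p = 0.0597). The median was -0.20, and ran from -0.845 without replicate 4 of both groups to 0.051 at a TPM minimum of 5. The fallen genes c1qb and c1qc also belong to the macrophage list. isg15, an interferon-induced gene, fell from 97.2 ± 36.1 to 10.1 ± 4.05 TPM, while the complement gene c4 rose from 27.8 ± 13.7 to 212 ± 48.7 TPM, a log2 fold change of 2.99 ± 0.43 (SE, adjusted p = 0.0024).

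Heat-shock and immediate early genes, which cells switch on within minutes to hours of stress or dissociation, were much higher at 60 dpi. Of 45 tested, 24 rose and none fell, or 31 and 2 over the list alone (median 1.57; camera adjusted p = 9.06e-22; adjusted p = 0.106 with an estimated correlation). FOS, a transcription factor gene induced by stimulation, rose from 510 ± 88.1 TPM (SD, n = 4) to 6898 ± 1030 TPM (SD, n = 3), a log2 fold change of 3.76 ± 0.24 (SE, limma adjusted p = 2.3e-05). HSPB1, a small heat-shock protein gene, rose from 441 ± 142 to 8356 ± 1396 TPM, a log2 fold change of 4.28 ± 0.28 with the same adjusted p. FOSL1 rose from 67.2 ± 5.37 to 674 ± 61.6 TPM and BTG2 from 50.5 ± 15.1 to 374 ± 52.4 TPM. Summed TPM of the list was 12871 at 7 dpi and 57839 at 60 dpi. CCN1, named above, is itself an immediate early gene, and its rise went with that of this list in the same libraries. MYC, also named above, is a member of the list.

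Few markers of the other cell types that the sort could hold passed the test. Of 36 cardiomyocyte genes 2 rose, tcap and MYL7, and none fell, or 1 and none over the list alone (median 1.12; camera adjusted p = 0.000193; adjusted p = 0.498 with an estimated correlation). The median was 2.173 without 60 dpi replicate 1 and 0.688 and 0.695 without replicates 2 and 4. MYL7, an atrial and ventricular myosin light chain gene of the fish heart, had 163 ± 78.1 TPM at 7 dpi and 968 ± 670 TPM at 60 dpi (195, 1389 and 1319 in replicates 1, 2 and 4; limma adjusted p = 0.0467), and its call was lost in 14 of 20 alternatives. TNNT2 (ENSDARG00000020610), cardiac troponin T, had 127 ± 72.2 and 707 ± 542 TPM (adjusted p = 0.16). Of 33 endothelial genes cd34 rose, from 73.4 ± 17.4 to 257 ± 37.0 TPM, and none fell, or 2 each way over the list alone (camera adjusted p = 0.185; median 0.40). kdrl, an endothelial receptor gene, had 2.13 ± 0.33 and 5.07 ± 3.57 TPM (adjusted p = 0.662). Of 25 cartilage, bone and tendon genes MATN4 rose, and none fell, or 3 and 1 over the list alone (camera adjusted p = 0.0248; median 1.03; adjusted p = 0.216 with an estimated correlation). That call was lost without 7 dpi replicate 1 (adjusted p = 0.0547) and without 60 dpi replicate 4 (0.0623, with a median of 0.512). None of 14 neural crest, Schwann cell and neuron genes passed, over all genes or over the list alone (limma; 4 at an unadjusted p under 0.05; camera adjusted p = 0.866, directed upward; median -0.01, above 0 with quantile normalization).

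**Figure D2:**
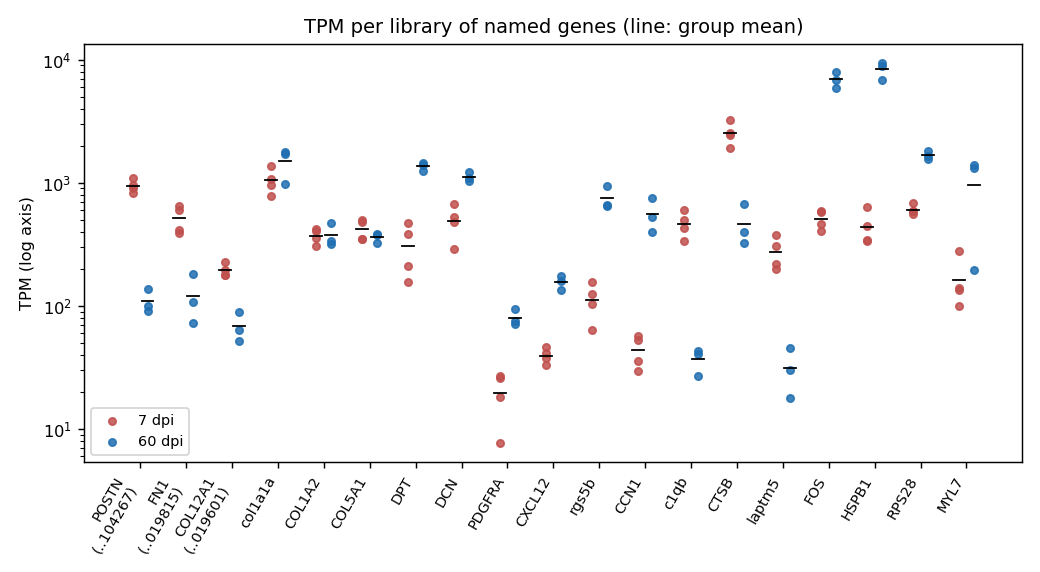
TPM per library, on a log axis, of 19 named genes, with one point per library coloured by time after injury and a line at each group mean. POSTN (ENSDARG00000104267) lies near 948 TPM at 7 dpi and 109 TPM at 60 dpi, COL1A2 overlaps at 372 and 375 TPM, and MYL7 spreads widely at 60 dpi.

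**Figure D3:**
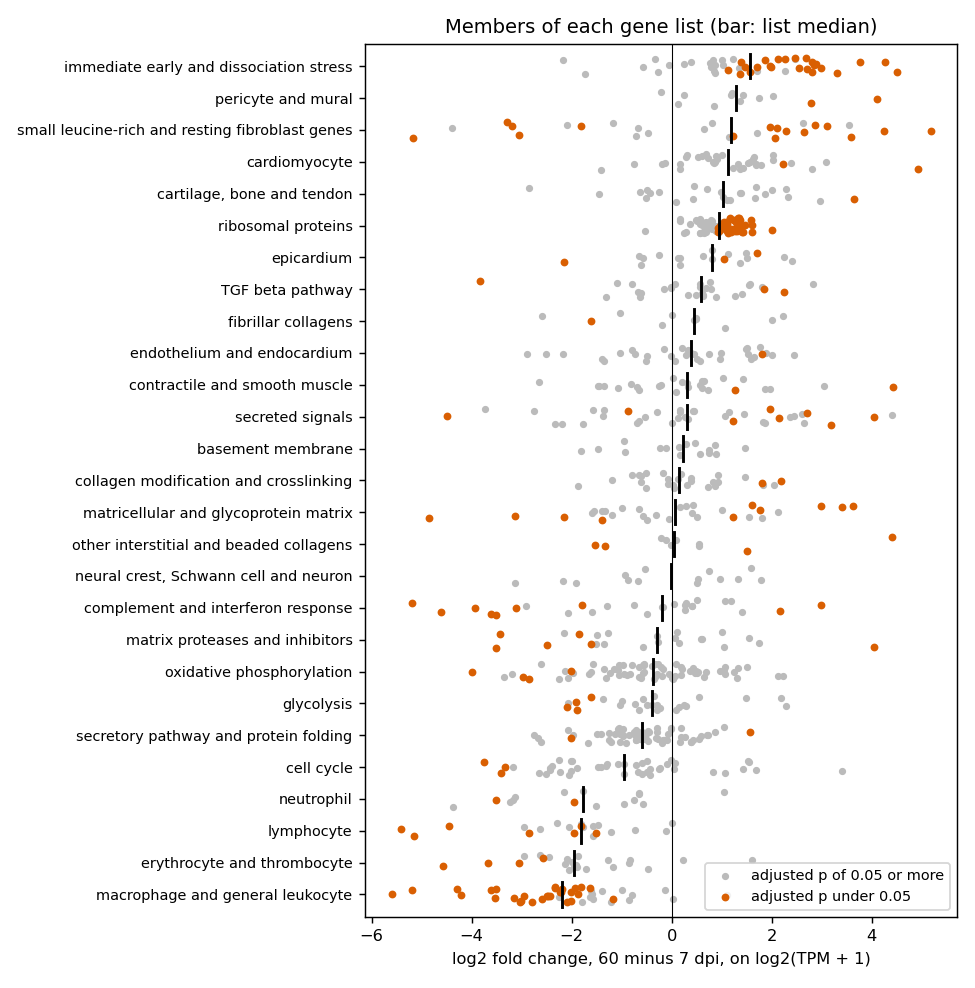
log2 fold change of 60 minus 7 dpi, on log2(TPM + 1), of every tested member of the 27 gene lists, with a bar at each list median and members of adjusted p under 0.05 in orange. The stress list has the highest median (1.57) and the macrophage and leukocyte list the lowest (-2.19); the medians of the fibrillar collagen, other collagen, matricellular, crosslinking, complement and neural lists change sign under some alternatives.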

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

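Within the 7 dpi group, the extreme library was compared with the other 3 by Dixon's ratio, the gap to its nearest neighbour over the whole range, against the 95% limit for 4 samples; chance passes this limit in about 1 of 20 cases, and 10 of 166 measures and genes did, where chance gives about 8.3. For genes the ratio was computed on log2(TPM + 1), while TPM values are printed below, so the printed values do not reproduce it. Tests of composition, dilution, cell share and handling below were chosen after the results were seen, and the handling test of stress genes, the composition tests of leukocyte and resting fibroblast genes and the dilution test of the latter replaced earlier forms that used only their called members.

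At 7 dpi replicate 4 had the fewest detected genes, 9844 against 14599 to 15431 in the other libraries (ratio 0.851), and replicate 2 the lowest share of TPM in mitochondrial transcripts, 2.46% against 3.04 to 3.08% (0.935). Replicate 2 was lowest for tnfa, at 32.2 TPM against 82.1 to 96.8 (0.849), and highest for COL11A1, at 12.1 TPM against 3.54 to 4.31 (0.852). Replicate 4 was highest for CTHRC1 (ENSDARG00000087198), at 93.9 TPM against 24.5 to 24.9 (0.987), and lowest for TNC (ENSDARG00000021948), at 1.51 TPM against 14.3 to 18.2 (0.888), and for SOX9 (ENSDARG00000003293), at 2.80 TPM against 17.6 to 24.0 (0.843). Replicate 1 was highest for CLDN5 (ENSDARG00000014059), at 51.4 TPM against 15.6 to 18.4 (0.864), and for krt94, at 486 TPM against 338 to 353 (0.883), and lowest for pmp22a, at 54.9 TPM against 137 to 162 (0.846).

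The count of 1041 changed genes was reached by 1 of the 35 splits of the 7 libraries into 4 and 3, the real one. The highest other split gave 3 genes. With 35 splits no share below 1 of 35 can occur, so chance was made unlikely but not excluded. Splits that mix the groups also widen the spread within each, which lowers their counts.

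Of 45 heat-shock and immediate early genes 24 were higher at 60 dpi and none lower (list median 1.57; camera adjusted p = 9.06e-22, and 0.106 with an estimated correlation). IDs without a symbol took 31.2% of TPM at 7 dpi and 17.4% at 60 dpi. Rescaling without them can move a list median only by a small amount, which these shares fix. The median was then 1.30 (95% bootstrap interval 0.885 to 1.86), so this part of the composition accounts for a small part of the rise. The list median was 1.514 with median ratio scaling and 1.392 with quantile normalization. Dilution of the labelled cells by other cells at 7 dpi would raise abundant fibroblast transcripts alike, if their level per cell stayed the same. The list median lay 1.29 above that of 8 collagen I, V and VI genes (0.28, interval -0.10 to 0.49). Expression per cell was not measured, and some other matrix genes fell while others rose, so dilution is not excluded. Handling or dissociation of the hearts on their collection days and a lasting state of the cells cannot be told apart, because no label gives a collection day; 31 members of the list were higher in every 60 dpi than in every 7 dpi library, as either would give. A difference between the time points in the cells themselves stays open and untested.

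Of 43 leukocyte genes 29 were lower at 60 dpi and none higher (list median -2.19; camera adjusted p = 4.1e-27, and 0.0772 with an estimated correlation). A lower share of every other cell type would lower all their markers alike, but the endothelial median lay 2.58 above the leukocyte median and the cardiomyocyte median 3.31 above it. The permutation p of the endothelial difference was 1e-05, the smallest that 100000 resamples can give. It shuffled genes between the 2 lists as if they were independent, so it does not measure the spread between pools. Stress and ribosomal genes took 8.15% of TPM at 7 dpi and 19.74% at 60 dpi, which lowers all other values at 60 dpi. Rescaling over the IDs outside these lists can move a list median only by a small amount, which these shares fix. The list median was then -2.02 (95% bootstrap interval -2.25 to -1.62), and that of all genes 0.08. This part of the composition therefore accounts for a small part of the fall. The list median was -2.237 with median ratio scaling and -2.315 with quantile normalization. What stays open is whether leukocytes entered the sort at 7 dpi, although the gate was set on mCherry, or whether labelled cells themselves used these genes; neither was tested.

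Of 28 resting fibroblast genes 11 were higher and 5 lower at 60 dpi (list median 1.19, 95% bootstrap interval -0.689 to 2.19; camera adjusted p = 0.037, and 0.216 with an estimated correlation). If collagen expression per cell stayed the same, fewer other cells at 60 dpi would raise abundant collagens by as much. The list median lay 0.91 above that of the 8 collagen I, V and VI genes, within the spread of the list. With TPM rescaled over IDs with a symbol the list median was 0.98 (interval -0.959 to 1.93) and the camera call was kept (adjusted p = 0.0457), but median ratio scaling (median 1.11, adjusted p = 0.0585) and quantile normalization (1.09 and 0.168) ended it, for a reason that was not tested. Dilution, a shift of the TPM scale and a change in the labelled fibroblasts cannot be told apart for the full list, because members went both ways and these intervals include 0. Of the 5 lower members 4 were IDs named MFAP4. Without the 6 tested MFAP4 IDs, left out after their values were seen, 11 rose and 1 fell. The median was then 2.02, against 0.28 for the collagens. The shortened list was not rescaled or bootstrapped, and collagen expression per cell was not measured, so the question stays open for it too. A difference between the time points in the cells themselves stays open and untested.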

How the results depend on the processing

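Alternatives that were added after seeing the data are those with TPM rescaled over IDs with a symbol, with IDs without a symbol left out and TPM not rescaled, without replicate 4 of both groups, with equal IDs counted once, and without MFAP4. No result changed direction past its threshold under any alternative, and the cause of each change below was not tested except where fewer libraries or more tested genes entered by construction. TPM keeps no depth, so what depth limits could not be measured. More genes were lower than higher in the main setting, but more were higher without 7 dpi replicate 1 (410 and 302) and at a pseudocount of 5 (539 and 516).

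The number of changed genes was 596 (266 higher, 330 lower) with no filter, which tests 23319 genes, and 1659 with library quality weights (938 lower). Leaving out single libraries gave 571 (without 7 dpi replicate 3) to 1127 (without 7 dpi replicate 4) changed genes, 213 (without 60 dpi replicate 2) to 458 higher and 292 to 669 lower; totals moved by over 1.5 times also without 7 dpi replicate 2 (643) and 60 dpi replicate 2 (580). The other settings gave 839 to 1288. Same-numbered libraries of the groups correlated at 0.005, 0.014 and 0.028 after the group means were removed, and libraries of different numbers at -0.024 to 0.019. These values show no clear pairing, but so few pairs cannot exclude a shared day or batch. The second principal component set replicate 4 of both groups apart. With a replicate block, which leaves out 7 dpi replicate 3, 300 genes passed (138 higher, 162 lower), against 571 in those 6 libraries with no block. Under the block, oxidative phosphorylation passed (0.0332) and glycolysis did not (0.0598); no other list call changed.

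Adjusted p of lists with camera and an estimated correlation were 0.0772 for pericytes, macrophages, neutrophils and lymphocytes, 0.106 for stress genes, 0.121 for ribosomal proteins, 0.19 for the cell cycle and for erythrocytes and thrombocytes, 0.216 for resting fibroblast genes, TGF beta and cartilage, and 0.498 for the secretory pathway, glycolysis and cardiomyocytes; no list passed. The estimated correlation was -0.0602 for pericytes and -0.0224 for neutrophils, below the preset 0.01, and 0.017 for resting fibroblast genes, close to it. A higher correlation therefore does not account for the lost calls of pericytes and neutrophils. With fry, TGF beta and cartilage (0.0575), the secretory pathway (0.13), glycolysis (0.143) and cardiomyocytes (0.302) did not pass, and crosslinking and proteases (0.0478), epicardium (0.0215) and complement (0.0058) did. Resting fibroblast genes gave 0.0693 at a TPM minimum of 5, 0.0585 with median ratio scaling, 0.168 with quantile normalization, 0.0842 with weights and 0.11 without replicate 4 of both groups. Without replicate 4 of both groups glycolysis gave 0.0591, cardiomyocytes 0.11 (median 0.521) and cartilage 0.0646 (median 0.569). At a TPM minimum of 5 TGF beta gave 0.0555 and cartilage 0.133, and with weights the secretory pathway 0.0522. With no filter crosslinking (0.0387), epicardium (0.00964) and complement (0.0485) passed, as did epicardium at a pseudocount of 0.1 (0.0489), proteases with median ratio scaling (0.043), and proteases (0.0206), oxidative phosphorylation (0.0103) and complement (0.0295) with quantile normalization. With TPM rescaled over IDs with a symbol, proteases (0.0254) and oxidative phosphorylation (0.0331) passed.

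Leaving out single libraries changed the call of 8 lists, whose adjusted p then ran from 0.0145 to 0.0623 for cartilage, from 0.0348 to 0.101 for complement, from 0.0395 to 0.118 for epicardium, from 0.0144 to 0.149 for glycolysis, from 0.0439 to 0.136 for proteases, from 0.0144 to 0.271 for oxidative phosphorylation, from 0.0167 to 0.113 for resting fibroblast genes, and from 0.00871 to 0.0593 for TGF beta. List medians that passed moved by over 1.5 times with the pseudocount for lymphocytes (-3.909 at 0.1 and -1.051 at 5, against -1.81), the cell cycle (-1.835 and -0.451, against -0.95), neutrophils (-0.731 at 5, against -1.78) and cartilage (0.609 at 5, against 1.03), and in other settings for the cell cycle (-1.469 at a TPM minimum of 5, -0.609 with quantile normalization), TGF beta (0.335) and glycolysis (-0.625) with symbol-based scaling, ribosomal proteins (0.492) with quantile normalization, and cardiomyocytes (0.718) and cartilage (0.65) with weights. The same held for cardiomyocytes (0.521, against 1.12) and cartilage (0.569) without replicate 4 of both groups. Leaving out single libraries also moved the medians of the basement membrane, other collagen, matricellular, crosslinking, protease, contractile, secreted signal, oxidative phosphorylation, complement, endothelial and neural lists, none of which passed in the main setting, by over 1.5 times. Proteases passed without 60 dpi replicate 1 (0.0439), epicardium without 7 dpi replicate 4 (0.0395), oxidative phosphorylation without 7 dpi replicate 3 (0.0302) or 60 dpi replicate 2 (0.0144), and complement without 60 dpi replicate 4 (0.0348).

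Of 161 genes named here, by the rule or outside it, 109 passed in the main setting. The 109 include RBP4, krt91, krt15, c6.2, vmo1a, BAG3, cd9b, FKBP5, nr1d2a, CEBPD, sgk1, hlfa and BHLHE41 from outside the rule, so genes picked after their values were seen add to the tally. Of the 109, 65 passed in all 20 alternatives that tested them, 27 failed in 1 to 6 and 17 in 7 or more: MYL7, plk1, SDHD (ENSDARG00000030139), TGFB3, DCN, mpl, ndufc2, P4HA2, RRM2 (ENSDARG00000020711), TGFBR3, cox6b1, krt94, tpm4a, MMP9, col11a1b, col16a1 and COX5B (ENSDARG00000015978). Each library left out ended between 10 (7 dpi replicate 4) and 22 (60 dpi replicate 2) of the 109 calls. Genes detected differed by -1044 between groups at a TPM of 1, by -1505 at 0.1 and by 9.2 at 5, none past the spread (exact permutation p of 0.514, 0.514 and 1). Libraries of a group exceeded those of different groups on average by 0.124 in Pearson and 0.137 in Spearman correlation.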

Other observations

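Several large changes lay outside the rule for named genes and were chosen after their values were seen. RBP4, which encodes a retinol carrier, rose from 312 ± 62.4 TPM (SD, n = 4) to 4122 ± 927 TPM (SD, n = 3), a log2 fold change of 3.72 ± 0.26 (SE, limma adjusted p = 3.57e-05). The keratin genes krt91 and krt15 rose from 27.9 ± 7.15 to 419 ± 83.5 TPM and from 196 ± 49.4 to 924 ± 93.1 TPM. The complement gene c6.2 rose from 459 ± 124 to 2126 ± 319 TPM, and vmo1a from 61.7 ± 17.4 to 813 ± 235 TPM. BAG3, a partner of heat-shock proteins, rose from 37.2 ± 10.6 to 697 ± 180 TPM. The tetraspanin gene cd9b fell from 326 ± 109 to 18.9 ± 4.25 TPM. In each of these genes every library of one group lay above every library of the other.

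The 2 hypotheses that follow were chosen after the values of their leading genes, and of tsc22d3, PER1 and DDIT4, were seen. The genes that lead the first are known targets of glucocorticoids, the stress steroids: FKBP5 rose from 27.8 ± 5.31 to 370 ± 97.9 TPM (limma adjusted p = 0.000161), beside KLF9, ZBTB16, GLUL (ENSDARG00000099776) and HSD11B2 above. A list of other genes known to respond to glucocorticoids, without these 5, was written before it was tested. Its 25 tested members had a median log2 fold change of 1.48, 5 rose and none fell (camera adjusted p = 9.22e-06 over 3 lists), and the unadjusted p was 0.004 with an estimated correlation. CEBPD rose from 11.4 ± 8.46 to 152 ± 20.3 TPM and sgk1 from 103 ± 19.6 to 295 ± 10.3 TPM, whereas the classical target tsc22d3 had a log2 fold change of 0.25 ± 0.49 and did not pass. Only 1 member also belongs to the stress list, and the median was 1.53 over the 21 members left without it and without the 3 genes already seen (unadjusted camera p = 4.35e-06, and 0.00399 with an estimated correlation). Leaving out shared members does not separate a glucocorticoid signal from the stress response that rose in the same libraries. Under the 3 other scalings the median of the 25 ran from 1.26 to 1.43. A stronger glucocorticoid signal at 60 dpi is therefore a candidate explanation, which may reflect the handling of fish or hearts as well as time after injury, and the 2 were not tested apart.

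The second hypothesis was that hearts were collected at another time of day at 60 dpi, since the clock gene nr1d2a rose from 11.5 ± 1.27 to 131 ± 46.0 TPM (limma adjusted p = 0.00106). The 15 other clock output genes had a median of -0.03 (camera adjusted p = 0.48), with hlfa higher and BHLHE41 lower, and the 6 tested genes of the positive arm, which should move the other way, had a median of 0.41 (camera adjusted p = 0.287). Members of the output list went both ways, so its median decides nothing, and another time of day stays open; the bounds of this test were rewritten after its values were seen.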
